A study of Mus musculus with 22 samples.

How the data were processed

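Liver RNA of 22 male mouse offspring in 4 groups was hybridised to Illumina BeadChips, 1 array per mouse. Per the labels' protocols, female mice of 5 weeks were assigned to the diets, mated after 6 weeks, and male offspring were fed for 24 weeks. RNA was extracted with TriReagent, checked on an Experion analyser, and biotin-labelled with the Illumina TotalPrep kit, per the labels. The deposited non-normalized table gives, for each of 45281 probes and each array, an intensity and a detection p-value. The intensity values had a background already subtracted, since between 33.2% and 41.2% of probes per array lay below 0, and no normalization between arrays is recorded in the file headers. The deposited series matrix holds a further intensity per probe and array, on a linear scale with array medians of 245, normalized between arrays by a method not given in the sources used here. Each of its 22 columns correlated best with the unnormalized values of the same array, and it was used as an alternative. Its centring and any adjustment for slide are not stated.

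The intensities were background-corrected and quantile-normalized with neqc of limma 3.58.1 (R 4.3.3), which infers the negative-control level from the detection p-values, with an offset of 16, and were put on a log2 scale. Probe names of the table were matched to current symbols through a RefSeq gene table (assembly GRCm38.p6, used for names only): 35713 probes (78.9%) matched 1 gene, 27399 by symbol and 8314 by a synonym, 191 matched several and 9377 matched none. No coordinates are given because the probe positions were not used here. A probe was kept where its detection p was under 0.05 on at least 5 arrays, which left 16268 probes, 14409 of them named. For each gene the named probe with the highest mean was used, giving 9881 genes. Tnf, Ccl2 and Cd36, which had been fixed for naming, were not tested because they did not meet the detection filter. Depth on arrays is the signal over background: genes near background have compressed differences, and array numbers limit precision.

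Group means were fitted to all 22 arrays with lmFit and eBayes, giving 1 shared estimate of the spread, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were LW against LL and WW against WL (diet after weaning), WL against LL and WW against LW (maternal diet), their interaction, and both averages. In addition 33 gene lists, covering liver metabolism, stress and inflammation, cell types of the liver and tissues that can be carried over, were fixed before the data were examined, and 32 with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted within each comparison. Each was repeated with an estimated correlation and with fry, which tests whether a list's genes move on balance one way. By fry, 4 lists passed in WW against WL, 6 in the average after weaning and 0 in each of the 5 other comparisons. A list score is the mean over its genes of the log2 difference from the LL mean. Scores were compared by exact two-sided permutation over 462 splits, adjusted over 33 lists, a test chosen after seeing the data. These splits did not keep to the slides, which the groups fill unevenly, so they do not part diet from slide.

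Genes were named by a rule fixed before the data were examined: for each simple comparison and the interaction, the 10 highest and 10 lowest differences among called genes, or the 5 smallest p-values where fewer than 5 passed, then up to 4 members of each list with the smallest p, and a few genes fixed in advance. Unnamed gene models were skipped. Some single-gene results are not reported here. The genes in the text are a subset of those the rule allows, picked for length after their values were seen. Outside the rule, and also picked after their values were seen, were the genes named for the average after weaning, Srd5a1, Lrfn3 and Cyp17a1 in WW against WL, Apob in LW against LL, and Bcl7a and Ccp110 in WW against LW. The functions were tested on simulated data drawn from the real means and spreads of 9881 genes with 200 genes changed: of genes changed by 2 on the log2 scale, 100% were recovered in LW against LL, 98.5% in WW against WL, 97.0% in WL against LL and 100% in WW against LW. Of genes changed by 0.5, 28.4%, 35.8%, 26.9% and 38.8% were recovered in this order. In the interaction 5.97% were recovered at 0.5 and 65.7% at 1. The simulated noise was independent between genes and held no slide differences, and with fewer changed genes the adjusted p is stricter. Slides were tested as a batch. The median F for slide over genes was 2.04, where 0.826 is expected without a difference, so slide was tried as a fixed block and, chosen after seeing the data, as a random block (duplicateCorrelation, genes only). Leaving out LL replicate 1 and WL replicate 5 together was also chosen after seeing the data. The estimated correlation was fixed beforehand as a companion test and was added to the alternatives afterwards.

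Other alternatives were the deposited values, no further background correction (values shifted to a lowest value of 16), normexp with an offset of 50, median scaling, no detection filter, a detection p under 0.01 on every array of a group, all detected probes, a replicate block, array weights, only the compared groups, a variance trend, and leaving out each array. Figures were drawn with matplotlib 3.10.9.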

Results

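Gene expression was measured in liver RNA of 22 male C57BL/6J mice, an inbred strain, at 29 weeks of age, each on its own array. The series title names susceptibility of adult male offspring to liver inflammation after a maternal western diet. Dams received a western diet (W) or a low-fat control diet (L), and their male offspring received W or L for 24 weeks. The first letter of each group is the diet of the dam and the second is that of the offspring, giving LL (n = 6), LW (n = 5), WL (n = 5) and WW (n = 6). The series text states that 1 experimental and 1 biological outlier had been excluded by the submitters. The labels describe separate offspring and give no litter, so the p-values treat each mouse as independent. The arrays detected between 13285 probes (LW replicate 2) and 15105 probes (WW replicate 6) of 45281, and their mean signal ran from 151 intensity units (LL replicate 1) to 276 (WW replicate 6). The arrays lay on 4 slides. Slide 1 held 1 LL, 2 LW and 2 WW arrays, slide 2 held 2 LW, 2 WL and 2 WW, slide 3 held 2 LL, 1 LW and 2 WL, and slide 4 held 3 LL, 1 WL and 2 WW. For most comparisons, gene counts and list medians with slide as a block stand beside those without it, because intensities differed between slides. For single genes such values are given only in part. The number of arrays limits the precision of every value. In all, 9881 genes and 32 gene lists were tested in each comparison with limma, and log2 differences are given with their standard error.

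The first question was what a western diet after weaning changed in offspring of low-fat dams (LW against LL). Cyp2b13, a cytochrome P450 expressed mainly in female mouse liver, was higher in LW (log2 difference 3.14 ± 0.51 SE, adjusted p = 0.00625). It was detected on 5 of 5 LW arrays and 1 of 6 LL arrays, so most LL arrays were at background, the log2 difference is one against background, and no fold is given. Cyp4a12b, a male-typical fatty acid hydroxylase, was 7.03-fold lower (-2.81 ± 0.46, adjusted p = 0.00625), and Srd5a1, a steroid 5-alpha-reductase, was 2.57-fold lower (-1.36 ± 0.18, adjusted p = 0.00066). Tpm2, a tropomyosin (1.70 ± 0.31), the neutrophil-attracting chemokine Cxcl1 (1.51 ± 0.30), the lipogenic transcription factor Srebf1 (1.12 ± 0.24), Syt1 (0.98 ± 0.20) and the ketone body enzyme Bdh1 (0.72 ± 0.14) also rose. The steroid hydroxylase Cyp17a1 (-1.92 ± 0.41), the acyl-CoA thioesterase Acot1 (-1.43 ± 0.29), Lmo4 (-1.01 ± 0.19), the manganese transporter Slc30a10 (-0.93 ± 0.19) and Smim1 (-0.89 ± 0.14) fell.

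In total 24 of the 9881 genes passed an adjusted p of 0.05 in LW against LL, 9 higher and 15 lower. With the deposited values 0 genes passed, and with no detection filter 7. With slide as a block 5 genes passed, all among the 24: Srd5a1 (-1.25, adjusted p = 0.00805), Cyp4a12b (-2.95, 0.0357), Cxcl1 (1.80, 0.0357), Slc30a10 (-1.06, 0.0357) and Smim1 (-0.83, 0.046). Within slides 1 and 3, which held both groups, LW minus LL was -2.84 and -3.90 for Cyp4a12b, -1.29 and -1.37 for Srd5a1, 1.81 and 4.67 for Cyp2b13, and 2.53 and 1.45 for Cxcl1. The only LL array on slide 1 was LL replicate 1, with the lowest mean signal (151). The only LW array on slide 3 was LW replicate 5. Each of these differences thus rests on 1 array on one side. Cyp2b13, Cyp4a12b, Srd5a1 and Smim1 passed whichever single mouse was left out, and each other named call was lost without at least 1 mouse. The call was kept in 4 of 22 cases for Lrfn3, 6 for Srebf1, 7 for Cyp17a1 and 10 for Clock, and in 15 to 20 for the others. Leaving out 1 mouse gave from 4 genes (without LW replicate 5) to 85 (without LL replicate 1).

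The fatty acid oxidation list covers the breakdown of fatty acids and also holds acyl-CoA thioesterases such as Acot1 and fatty acid hydroxylases such as Cyp4a14. Of its 26 tested genes, 22 were lower in LW than in LL, with a median of -0.42. The list was called by camera (adjusted p = 9.77e-07), not with an estimated correlation (adjusted p = 0.36). Over all genes 1 of them, Acot1, passed, and adjusted over the list alone 12 did. Members that did not pass over all genes were Acot2 (-0.92 ± 0.24, detected on 4 of 5 LW arrays), Cyp4a14 (-0.87 ± 0.23) and Acadl (-0.68 ± 0.19). Its score per mouse was -0.46 ± 0.13 (SD, n = 5) in LW against 0.15 SD (n = 6) around 0 in LL (exact two-sided permutation adjusted p = 0.0238). With slide as a block the median was -0.29. Within slides 1 and 3 the score differed by -0.38 and -0.30, with LL replicate 1 and LW replicate 5 as the single arrays. Male-biased liver genes were lower in 15 of 21 cases (median -0.35, -0.33 with slide as a block, camera adjusted p = 0.000372, adjusted p = 0.475 with an estimated correlation, exact two-sided permutation adjusted p = 0.155), adjusted over the list alone 6 passed, and Elovl3 (-1.37 ± 0.32) and Mup5 (-1.23 ± 0.31) did not pass over all genes. Without LL replicate 5 or LW replicate 5 the male-biased median was -0.21 or -0.22, and the call was kept. Female-biased genes were not called by camera. Their score was higher in LW by 0.65 (exact two-sided permutation adjusted p = 0.0893), while their member Cyp17a1 fell.

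Genes of the circadian clock were higher in 12 of 14 cases in LW (median 0.46, 0.46 with slide as a block), with Ciart at 1.96 ± 0.53 (detected on 5 of 6 LL arrays) and Dbp at 1.39 ± 0.33, which did not pass over all genes, while Clock itself fell (-0.61 ± 0.13). Camera called this list (adjusted p = 0.00435), not with an estimated correlation (adjusted p = 0.475) or by exact permutation of the scores (adjusted p = 0.183), and 7 members passed adjusted over the list alone, 6 higher and 1 lower. The time of day of collection is not among the sample details used here, so it was not considered for circadian genes in any comparison. The 5 tested adipose genes were all higher (median 0.39, 0.27 with slide as a block, camera adjusted p = 0.03, adjusted p = 0.36 with an estimated correlation, exact permutation adjusted p = 0.0238). Periportal hepatocyte genes (median -0.13), antigen presentation genes (-0.18) and acute phase genes (-0.14) were called lower by camera, with adjusted p of 0.0275, 0.03 and 0.03, of 0.475, 0.64 and 0.64 with an estimated correlation, and of 0.193, 0.256 and 0.437 by exact permutation. Methyl donor and epigenetic genes, not called by camera (median -0.016, adjusted p = 0.228), had a lower score in LW by -0.16 (exact two-sided permutation adjusted p = 0.0238), but 7 of the 17 were higher and 1 member, at -1.65, made up most of the difference. With 1 mouse left out, the call was kept in 21 of 22 cases for adipose, 19 for periportal, 18 for antigen presentation and 18 for acute phase genes, with the highest adjusted p without LL replicate 1 (adipose, 0.058, and periportal, 0.298, median -0.063), LL replicate 3 (antigen presentation, 0.154) and LW replicate 1 (acute phase, 0.254, median -0.078). Without LW replicate 5 the periportal median was -0.069 and the call was lost (0.0542). Still called but larger were antigen presentation without LW replicate 3 (-0.34) and acute phase genes without LW replicate 2 (-0.21). With slide as a block the periportal call was kept (median -0.17), and the adipose, antigen presentation (-0.26) and acute phase (0.0051) calls were not.

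The second question was what the same diet changed in offspring of western-diet dams (WW against WL). Hsd3b5, a male-specific steroid dehydrogenase of the liver, was 29.9-fold lower in WW (-4.90 ± 0.88, adjusted p = 0.013), at a log2 intensity of 6.52 ± 2.33 (SD, n = 6, detected on 5 of 6 arrays) against 11.42 ± 1.00 (SD, n = 5). With 1 mouse left out the log2 difference of Hsd3b5 ran from -5.76 to -4.56, so the fold is imprecise. Other male-typical genes fell with Hsd3b5: Cyp4a12b (-2.66 ± 0.46), Cyp2c54 (-1.97 ± 0.42, detected on 5 of 6 WW arrays), the fatty acid elongase Elovl3 (-1.79 ± 0.32) and the major urinary protein Mup4 (-1.72 ± 0.33). Female-typical Cyp2b13 rose (3.18 ± 0.51, adjusted p = 0.0102), detected on 6 of 6 WW arrays and 1 of 5 WL arrays, so that no fold is given here either. Tmem45b (2.05 ± 0.30, detected on 6 of 6 against 2 of 5 arrays), Fndc10 (1.92 ± 0.38), the glutathione transferase Gstm2 (1.32 ± 0.23), the hepcidin gene Hamp2 (1.32 ± 0.30) and the zinc transporter Slc39a4 (1.23 ± 0.25) rose as well. The vasopressin receptor Avpr1a (-1.94 ± 0.35), Acot1 (-1.56 ± 0.29), the epidermal growth factor receptor Egfr (-1.39 ± 0.30), the fatty acid hydroxylases Cyp4a31 (-1.33 ± 0.26) and Cyp4a14 (-1.15 ± 0.23), Srd5a1 (-1.01 ± 0.18) and Apob, the structural protein of secreted lipoproteins (-1.01 ± 0.20), fell.

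In total 47 genes passed in WW against WL, 22 higher and 25 lower, and with slide as a block 316 passed, 181 higher and 135 lower, the 47 among them. With the deposited values 125 genes passed, and with no detection filter 2. Within slides 2 and 4, which held both groups, WW minus WL was -5.59 and -6.15 for Hsd3b5, -2.67 and -3.52 for Cyp4a12b, 3.71 and 2.52 for Cyp2b13, -1.46 and -3.09 for Elovl3, and -1.15 and -1.25 for Apob. WL replicate 5 was the only WL array on slide 4, so each slide 4 value rests on it, as does part of the comparison with slide as a block. Its Elovl3 intensity was 12.16, against 10.54 or less in the other WL mice. With 1 mouse left out the Hamp2 call was kept in 10 of 22 cases, the fewest of the called genes named here. Without WL replicate 5 only 3 genes passed, Cyp2b13, Tmem45b and Srd5a1, and the adjusted p of Hsd3b5 was then 0.0575. This mouse also stood apart in markers of the exocrine pancreas, with a score of 1.24 against 0.30 or less in the other WL mice.

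All 21 tested male-biased genes were lower in WW than in WL, with a median of -0.82 (-0.91 with slide as a block). Over all genes 6 passed, and adjusted over the list alone 10 did. Camera called the list (adjusted p = 1.67e-15), also with an estimated correlation (adjusted p = 0.0312), and the score per mouse was -0.84 ± 0.31 (SD, n = 6) in WW against 0.26 ± 0.38 (SD, n = 5) in WL (exact two-sided permutation adjusted p = 0.0476), with differences of -0.99 and -1.66 within slides 2 and 4. The slide 4 value rests on WL replicate 5 as the only WL array, with a score of 0.84. The 7 female-biased genes had a median of 0.46 (0.50 with slide as a block, camera adjusted p = 0.00195, adjusted p = 0.106 with an estimated correlation, exact permutation adjusted p = 0.0476), 6 of them higher, and Cyp2b13 was the member that passed. Probes of the Cyp4a12, Mup and Cyp2b families can share signal between near-identical genes, so single members of these families are uncertain.

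Genes of lipid metabolism formed further lists that camera called, none of them with an estimated correlation. Fatty acid oxidation genes were lower in 20 of 26 cases (median -0.27, -0.24 with slide as a block, camera adjusted p = 8.74e-05, adjusted p = 0.296 with an estimated correlation), with Acot1, Cyp4a31 and Cyp4a14 passing over all genes and 4 members adjusted over the list alone. Lipogenesis genes (median 0.35, 0.43 with slide as a block, 13 of 17 higher) and lipid droplet and PPAR-gamma target genes (0.39, 0.82 with slide as a block, 11 of 15 higher) were called higher, with camera adjusted p of 0.00268 and 0.00376, and an adjusted p = 0.318 for both with an estimated correlation. Cidea (3.20 ± 0.86) and Cidec (1.95 ± 0.52), both proteins of the lipid droplet surface, Thrsp (1.93 ± 0.52), Pparg (1.02 ± 0.34) and Srebf1 (0.87 ± 0.24) did not pass over all genes, Cidea and Cidec being detected on 4 of 5 WL arrays. With slide as a block the first 4 of these did, with adjusted p of 0.0116, 0.00663, 0.0102 and 0.032. WL replicate 5, the only WL array on slide 4, was low in Pparg (6.66) and Thrsp (6.46), so these calls are not independent of that mouse. Cholesterol synthesis genes were higher in 14 of 19 cases (median 0.35, 0.31 with slide as a block, camera adjusted p = 0.00294, adjusted p = 0.318 with an estimated correlation), 2 members passing adjusted over the list alone and none over all genes. By exact permutation of the scores the adjusted p was 0.0929 for fatty acid oxidation, 0.0476 for lipogenesis and for lipid droplet genes, and 0.112 for cholesterol synthesis. Without WL replicate 5 the lipid droplet median was 0.058 (adjusted p = 0.0275), and without WW replicate 6 that of fatty acid oxidation was -0.18 (0.00166).

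Lists of cell cycle, fibrosis and some immune genes were higher in WW than in WL by camera, though none was called with an estimated correlation and no member passed over all genes. Neutrophil markers (median 0.076, adjusted p = 0.834) and interferon response genes (-0.041, 0.423) were not called. Cell cycle genes had a median of 0.50 (0.59 with slide as a block, 17 of 19 higher, 6 adjusted over the list alone, camera adjusted p = 1.48e-07, adjusted p = 0.199 with an estimated correlation), with Mcm5 at 0.74 ± 0.19 and Mcm2 at 0.74 ± 0.21. Fibrosis and matrix genes had a median of 0.46 (0.61, 26 of 30, 3.28e-06, adjusted p = 0.318 with an estimated correlation), with Lgals1 at 1.66 ± 0.55, the protease inhibitor Timp1 at 1.21 ± 0.40 and the collagen Col1a1 at 1.05 ± 0.37. Macrophage markers had a median of 0.33 (0.52, 23 of 24, 6.09e-05, adjusted p = 0.318 with an estimated correlation), with Gpnmb at 2.03 ± 0.85, and inflammatory mediators 0.28 (0.42, 21 of 25, 0.00268, adjusted p = 0.387 with an estimated correlation), with Lcn2 at 1.82 ± 0.67. Lymphocyte markers (0.21, 0.21 with slide as a block), antigen presentation genes (0.25 and 0.38) and antioxidant genes (0.045 and 0.11) were also called, with adjusted p of 0.0137, 0.0294 and 0.0045, and of 0.225, 0.499 and 0.301 with an estimated correlation. In WL, Mcm5 and Gsta1 were detected on 4 of 5 arrays and Mcm2, Timp1, Col1a1 and Gpnmb on 3. Of the antioxidant genes 8 passed adjusted over the list alone, and Gsta1 (2.75 ± 0.77), Gsta4 (1.17 ± 0.30), Cbr3 (1.56 ± 0.45) and Ephx1 (0.63 ± 0.15) did not pass over all genes. By exact permutation of the scores cell cycle, lymphocyte and antioxidant genes passed (adjusted p = 0.0476 for each), and fibrosis (0.143), macrophage (0.218), inflammatory (0.304) and antigen presentation genes (0.448) did not. Lipoprotein secretion and glucose and insulin genes, not called by camera (adjusted p = 0.0702 and 0.258), had lower scores in WW by -0.17 and -0.13 (exact permutation adjusted p = 0.0476 for both). The 5 adipose genes had a median of -0.067 and a mean of 0.92, of opposite sign, and were not called. Markers of endothelial cells (median 0.12) and cholangiocytes (-0.086) were not called. Without WW replicate 6 the inflammatory and antigen presentation calls were lost (medians 0.14 and 0.097, adjusted p = 0.112 and 0.421), and the medians of macrophage (0.22) and lymphocyte markers (0.13) were lower. Without WL replicate 1 the inflammatory, antigen presentation and lymphocyte calls were lost (medians 0.18, 0.17 and 0.20, adjusted p = 0.0616, 0.141 and 0.0506), and without WW replicate 4 that of antigen presentation (0.051). The antioxidant median, near 0, ran from 0.024 (without WW replicate 5) to 0.10 (without WW replicate 1).

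**Figure D1:**
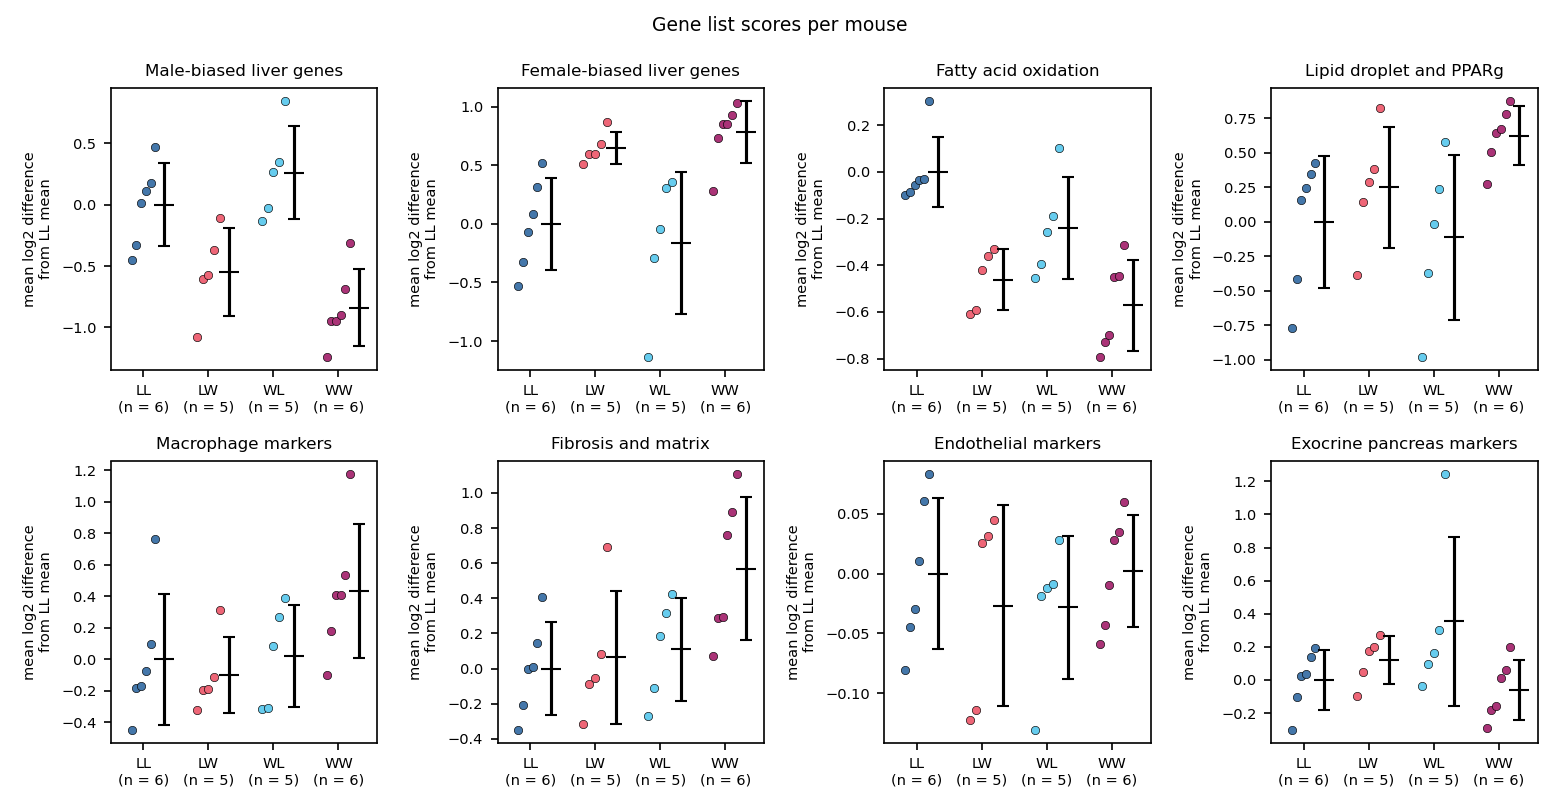
Score of 8 fixed gene lists in each mouse, as the mean log2 intensity difference of the list's tested genes from the LL mean (y axis), by group (x axis). Points are mice, and the bar beside them is the mean with 1 SD. The male-biased score was -0.84 ± 0.31 in WW and 0.26 ± 0.38 in WL, and WL replicate 5 stands at 1.24 in the exocrine pancreas score.

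Averaged over both maternal diets, the western diet after weaning changed 268 genes, 151 higher and 117 lower, and 248 with slide as a block, of which 144 were shared. Which of the genes named here are among the 144 is not reported here. Cyp2b13 rose (adjusted p = 3.2e-05), and no size is given, as it was detected on 1 of 6 LL and 1 of 5 WL arrays. Cidea (2.56 ± 0.61), Cfd, the complement factor adipsin (2.30 ± 0.59), Thrsp (1.57 ± 0.37), Srebf1 (1.00 ± 0.17), Pparg (0.99 ± 0.24), Cxcl1 (0.95 ± 0.21) and Gstm2 (0.91 ± 0.16) rose, Cidea being detected on 4 of 6 LL and 4 of 5 WL arrays and Cfd on 5 of 6 and 4 of 5. Cidea and Cfd also belong to the adipose list, whose mean score was 1.05 in LW, 1.16 in WW and 0.23 in WL, relative to the LL mean. Hsd3b5 (-3.17 ± 0.62, detected on 5 of 6 WW arrays), Cyp4a12b (-2.74 ± 0.32), Elovl3 (-1.58 ± 0.23), Acot1 (-1.50 ± 0.21) and Srd5a1 (-1.19 ± 0.13, adjusted p = 1.44e-05) fell. An average need not hold in each maternal background. Hsd3b5 stood at -4.90 in WW against WL but at -1.43 in LW against LL, where it did not pass (limma adjusted p = 0.45). Cxcl1 stood at 1.51 in LW against LL, above its average. Leaving out 1 mouse gave from 134 genes (without WL replicate 5) to 520 (without LL replicate 1), and Cidea, Cfd and Pparg no longer passed without at least 1 mouse (adjusted p up to 0.063, 0.0848 and 0.052). Their calls were kept in 20, 12 and 19 of 22 cases. The genes named for this average were chosen after their values were seen. By camera 10 lists were called, none with an estimated correlation, with male-biased genes at -0.77 (20 of 21 lower, adjusted p = 2.39e-12, and adjusted p = 0.0804 with an estimated correlation) and fatty acid oxidation at -0.30 (23 of 26 lower, 3.18e-08, and adjusted p = 0.179 with an estimated correlation). Their medians were -0.67 and -0.26 with slide as a block.

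The log2 differences of the western diet in the 2 maternal backgrounds had a Pearson correlation of 0.38 across genes (0.28 with slide as a block). Its jackknife standard error, from leaving out each mouse, was 0.24 without the block. Without effects of diet or slide the value would be 0, because no array is shared. The groups fill the slides unevenly, so slide differences can move both sets of differences alike. No value without effects was computed for the fit with slide as a block. Genes are not independent replicates. Over all genes 59.0% had the same sign in both comparisons. Of the 24 genes called in LW against LL, 20 had the same sign in WW against WL, and of the 47 called there 41 had the same sign in LW against LL. Of these genes 1 was called higher in both (0.020 in independent lists of these sizes) and 4 lower in both (0.038). The 2 sets of calls share 1 estimate of the spread of each gene, so they are not independent and the overlap was not tested. Cyp2b13 was higher in both, and Cyp4a12b, Acot1, Srd5a1 and Lrfn3 were lower in both.

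**Figure D2:**
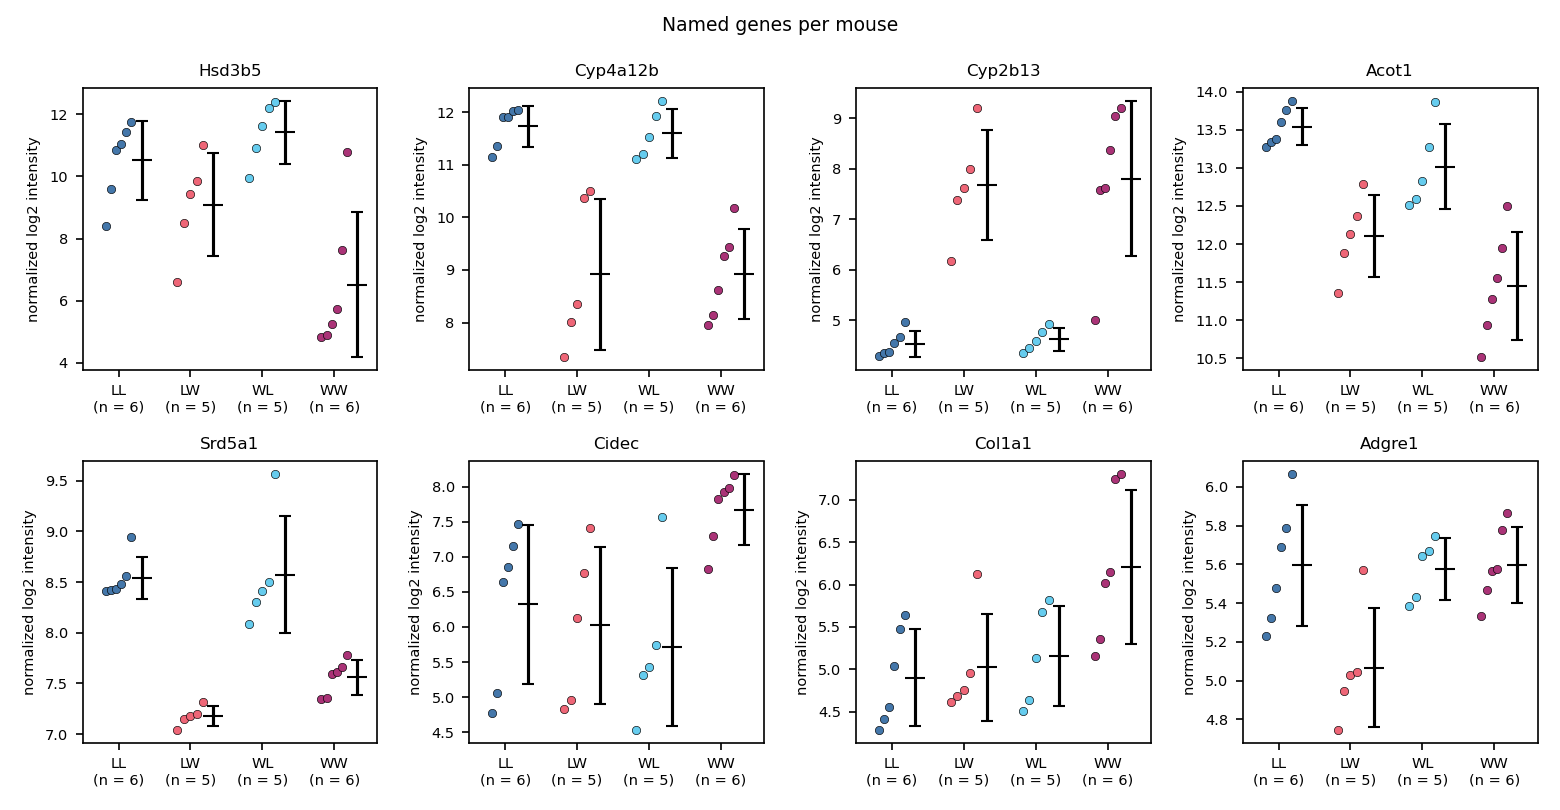
Normalized log2 intensity (y axis) of 8 named genes in each mouse by group (x axis). Points are mice, and the bar beside them is the mean with 1 SD. Hsd3b5 stood at 6.52 ± 2.33 in WW and 11.42 ± 1.00 in WL, and Cyp2b13 was higher in both groups fed the western diet after weaning.

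The third question was whether the maternal western diet left a difference in offspring fed the low-fat diet (WL against LL). No gene passed in limma, with or without slide as a block, and 468 genes had an unadjusted p under 0.05, where chance gives 494. The smallest p-values belonged to Dip2c (0.65 ± 0.12, adjusted p = 0.109), the arrestin-like Arrdc3 (1.33 ± 0.26), the lysophospholipid transporter Mfsd2a (-1.73 ± 0.37), Zfp868 (0.55 ± 0.12) and Tshz2 (0.63 ± 0.15), none of which passed. Dip2c, Zfp868 and Tshz2 were detected on 3, 1 and 1 of 6 LL arrays. Their differences were 0.58, 1.14, -1.66, 0.50 and 0.74 with slide as a block. Cxcl1 stood at 1.26 ± 0.30 and did not pass. On simulated arrays with these group sizes, 85.1% of genes changed by 1 on the log2 scale were recovered, and 26.9% of those changed by 0.5. With 200 changed genes and no slide differences, the simulation does not show the recovery where few genes change.

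Camera called 5 lists in WL against LL, none with an estimated correlation, where each had an adjusted p = 0.753, or by exact permutation of the scores, where each had an adjusted p = 0.919. Fatty acid oxidation genes were lower in 23 of 26 cases (median -0.14, -0.12 with slide as a block, camera adjusted p = 0.00135), with Acot2 at -1.0 ± 0.24 (detected on 4 of 5 WL arrays), Acot3 at -1.04 ± 0.46 and Pdk4 at -0.87 ± 0.37, and 1 member passed adjusted over the list alone. Male-biased genes were higher in 18 of 21 cases (0.22, 0.35 with slide as a block, 0.00631). Interferon response genes (0.13, 0.22 with slide as a block, 17 of 22 higher, 0.0346), with Ifi47 at 0.52 ± 0.16 (detected on 3 of 6 LL arrays), and circadian genes (0.23, 0.15 with slide as a block, 0.0357) were called higher. Cell cycle genes were called lower (-0.13, -0.15 with slide as a block, 0.0233), with the cell cycle inhibitor Cdkn1a at -1.41 ± 0.42. Without WL replicate 4 none of the lists was called, and each call was lost without some mouse. The call was kept in 21 of 22 cases for fatty acid oxidation, 19 for male-biased, 18 for cell cycle, 16 for interferon and 15 for circadian genes, with the highest adjusted p without WL replicate 4 (fatty acid oxidation, 0.108, median -0.058), WL replicate 5 (male-biased, 0.341, median 0.12), LL replicate 1 (interferon, 0.378, median 0.081, and circadian, 0.239, median 0.10) and LL replicate 3 (cell cycle, 0.551, median -0.0076). Other medians moved by over 1.5 times were fatty acid oxidation without LL replicate 6 (-0.077), interferon without WL replicate 1 (0.21), cell cycle without WL replicate 2 (-0.22), and circadian without LL replicate 2 (0.37), WL replicate 1 (0.13), WL replicate 3 (0.15) or WL replicate 5 (0.45). With 1 mouse left out, LW replicate 5 or WL replicate 4 or 5, 1 gene passed, and the circadian call was lost with slide as a block.

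The fourth question was whether the maternal diet made a difference in offspring that ate the western diet themselves (WW against LW). Macrophage markers were higher in 21 of 24 cases in WW, with a median of 0.53 (0.53 with slide as a block). Camera called the list (adjusted p = 2.49e-10), but not with an estimated correlation (adjusted p = 0.426). No member passed over all genes, and 8 passed adjusted over the list alone. Examples that did not pass over all genes were the complement components C1qa (0.46 ± 0.14) and C1qb (0.53 ± 0.17), Cd68 (0.54 ± 0.24), Ms4a7 (0.75 ± 0.24, detected on 2 of 5 LW arrays) and the macrophage surface receptor Adgre1 (0.53 ± 0.15, detected on 4 of 5). Adgre1 stood at 5.60 ± 0.20 in WW, 5.07 ± 0.31 in LW, 5.60 ± 0.31 in LL and 5.58 ± 0.16 in WL (SD), so that LW was the lowest group. The macrophage score was 0.44 ± 0.43 (SD, n = 6) in WW and -0.10 ± 0.24 (SD, n = 5) in LW, a difference of 0.48 within slide 1 and 0.35 within slide 2. The exact two-sided permutation test of the score gave p = 0.0281, 0.2 after adjustment over 33 lists.

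Fibrosis and matrix genes followed the same direction in WW against LW, 26 of 30 higher, with a median of 0.49 (0.58 with slide as a block, camera adjusted p = 9.62e-10, adjusted p = 0.438 with an estimated correlation) and 6 passing adjusted over the list alone. Col1a1 stood at 1.18 ± 0.37 (detected on 6 of 6 WW and 2 of 5 LW arrays), Timp1 at 1.15 ± 0.40 (6 of 6 and 3 of 5), Col6a3 at 0.99 ± 0.30, Col4a1 at 0.74 ± 0.23 and Col5a1 at 0.71 ± 0.21. Within slides 1 and 2 the score differed by 0.73 and 0.27. Antigen presentation genes had a median of 0.41 (0.52 with slide as a block, 13 of 14 higher, 2.46e-06, adjusted p = 0.426 with an estimated correlation), with the class II genes H2-Ab1 at 0.76 ± 0.26, H2-Aa at 0.69 ± 0.26 (detected on 2 of 5 LW arrays) and H2-DMa at 0.69 ± 0.23. Inflammatory mediators had a median of 0.39 (0.39 with slide as a block, 21 of 25 higher, 1.17e-05, adjusted p = 0.438 with an estimated correlation), with the inflammasome protease Casp1 at 0.56 ± 0.15 and the adhesion molecule Vcam1 at 0.80 ± 0.30. Without WW replicate 6 the medians of these 2 lists were 0.27 and 0.22, both still called. Without WW replicate 5 the antigen presentation median was 0.61.

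Smaller shifts were called in 8 further lists of WW against LW, none with an estimated correlation, at adjusted p of 0.377 for lymphocyte markers, 0.484 for lipid droplet genes and 0.438 for the others. Cell cycle (0.24, adjusted p = 0.00324), lymphocyte (0.26, 0.00358), interferon response (0.21, 0.00702), lipogenesis (0.31, 0.0139), lipid droplet (0.19, 0.0336) and antioxidant genes (0.11, 0.0488) were higher, and xenobiotic metabolism (-0.21, 0.0297) and endoplasmic reticulum stress genes (-0.16, 0.0494) were lower. Their medians in this order with slide as a block were 0.26, 0.24, 0.18, 0.34, 0.34, 0.099, -0.17 and -0.12, and the antioxidant and xenobiotic calls were lost. By exact permutation none of the 33 lists passed in WW against LW, and the smallest adjusted p was 0.179. Cidec (1.65 ± 0.52, detected on 4 of 5 LW arrays), the fatty acid elongase Elovl6 (1.05 ± 0.35), Cyp2c37 (-1.02 ± 0.28) and Cyp2c50 (-1.01 ± 0.32) did not pass. With 1 mouse left out, the call was kept in 20 of 22 cases for lipogenesis, interferon and xenobiotic genes, 17 for lipid droplet, 12 for endoplasmic reticulum stress and 11 for antioxidant genes. The highest adjusted p came without LW replicate 2 (lipogenesis, 0.244, median 0.16), LW replicate 1 (lipid droplet, 0.237, median 0.038), LW replicate 4 (endoplasmic reticulum stress, 0.409), WW replicate 2 (xenobiotic, 0.112) and WW replicate 6 (interferon, 0.0685, and antioxidant, 0.161). The lipid droplet median was 0.31 without LW replicate 3, 0.12 without WW replicate 4 and 0.10 without WW replicate 5, where the call was lost. The xenobiotic median was -0.33 without WW replicate 3, and the antioxidant one 0.076 without LW replicate 2 (adjusted p = 0.141). Markers of endothelial cells (median 0.039) and cholangiocytes were not called in this or any other comparison.

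No single gene passed in WW against LW in limma, where 989 genes had an unadjusted p under 0.05 and chance gives 494 on average. Genes are not independent, and the spread of this count by chance was not computed, so the excess was not tested. The smallest p-values belonged to Cyp2c54 (-2.08 ± 0.42), the anchor-attachment gene Pigt (-1.15 ± 0.24), Krt222 (-0.57 ± 0.12, detected on 2 of 6 WW arrays), Arhgdib (0.76 ± 0.17) and the histone demethylase Kdm6b (-0.79 ± 0.18), with adjusted p of 0.301, 0.301, 0.301, 0.308 and 0.421. With slide as a block 4 genes passed, all lower: Cyp2c54 (-2.23, adjusted p = 0.0328), Pigt (-1.10, 0.0296), and Bcl7a (-0.66, 0.0296) and Ccp110 (-0.56, 0.0296), which were chosen after their values were seen. Apob stood at -0.86 ± 0.20 and Hsd3b5 at -2.57 ± 0.88, neither passing. On simulated arrays, 91.0% of genes changed by 1 on the log2 scale were recovered in this comparison, and 38.8% of those changed by 0.5. These arrays held 200 changed genes and no slide differences, so recovery where few genes change is not shown.

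Whether the effect of the offspring diet depended on the maternal diet was tested by the interaction. No gene passed in limma, and 790 had an unadjusted p under 0.05 against 494 by chance on average, an excess that was not tested. The smallest p-values belonged to Dip2c (-0.86 ± 0.17, adjusted p = 0.266), Cnot11 (-0.93 ± 0.22), Arrdc3 (-1.53 ± 0.36), the arsenic methyltransferase As3mt (1.02 ± 0.25) and Syt1 (-1.12 ± 0.28). Cidec stood at 2.25 ± 0.74 and did not pass. Dip2c was detected on 3 of 6 LL and 5 of 6 WW arrays, and Cidec on 5 of 6 LL, 4 of 5 LW and 4 of 5 WL. By camera 10 lists were called, none with an estimated correlation (adjusted p = 0.481 for each), among them macrophage (0.48, 23 of 24 positive, adjusted p = 2.79e-06), cell cycle (0.40, 0.00014), antigen presentation (0.51, 0.000146) and fibrosis genes (0.39, 0.00118) with a higher value for the western diet after western-diet dams, and male-biased genes (-0.42, 0.00161) with a lower one. These medians with slide as a block were 0.55, 0.40, 0.66, 0.61 and -0.52. The other 5 lists were inflammatory mediators (0.44, adjusted p = 0.00516), lymphocyte markers (0.26, 0.00516), lipid droplet genes (0.32, 0.0076), lipogenesis (0.46, 0.0346) and circadian genes (-0.38, 0.015), each with an adjusted p = 0.481 with an estimated correlation. The inflammatory, lymphocyte and circadian calls were lost with slide as a block (adjusted p = 0.0514, 0.138 and 0.174). With 1 mouse left out, the call was kept in 13 of 22 cases for lipogenesis, 19 for circadian, 20 for lipid droplet and 21 for inflammatory genes, with the highest adjusted p without LW replicate 2 (0.273, median 0.22), LL replicate 1 (0.0838), WL replicate 5 (0.119, median 0.12) and WW replicate 6 (0.0806, median 0.21). Still called but smaller were antigen presentation without WW replicate 6 (0.33), fibrosis without WL replicate 5 (0.24) and male-biased genes without WW replicate 2 (-0.27). Without WL replicate 5 the lipogenesis call was also lost (adjusted p = 0.156, median 0.24). The lipid droplet median was 0.56 without LL replicate 1 and 0.48 without LW replicate 5 or WW replicate 1, the circadian one was -0.25 without WL replicate 1, and the inflammatory one was 0.28 without LW replicate 4.

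Averaged over both offspring diets, the maternal diet changed no gene in limma (582 with an unadjusted p under 0.05, 494 by chance on average, an excess not tested). Camera called 7 lists, none with an estimated correlation. Fibrosis (0.29, 28 of 30 higher, adjusted p = 1.24e-09), macrophage (0.26, 7.03e-07), inflammatory mediator (0.21, 0.000146), interferon response (0.17, 0.000146) and antigen presentation genes (0.22, 0.000937) were higher, and fatty acid oxidation (-0.13, 0.000189) and xenobiotic metabolism genes (-0.11, 0.00519) were lower, each with an adjusted p = 0.447 with an estimated correlation. The medians with slide as a block were 0.25, 0.23, 0.23, 0.18, 0.21, -0.12 and -0.11. List scores of WL minus LL in this order were 0.11, 0.024, 0.041, 0.13, -0.037, -0.24 and -0.077. Those of WW minus LW were 0.51, 0.53, 0.37, 0.19, 0.41, -0.11 and -0.20. The macrophage, inflammatory and antigen presentation averages thus came mainly from offspring fed the western diet. Without WL replicate 5 the xenobiotic call was lost (adjusted p = 0.0927), without LL replicate 1 its median was -0.069, and without WW replicate 6 the inflammatory median was 0.14. The maternal effects in the 2 offspring diets had a correlation of -0.061 across genes (-0.28 with slide as a block), and the 2 averaged effects one of 0.087 (0.28 with slide as a block), where the group sizes alone give -0.091 without the block. No value without effects was computed with slide as a block. The jackknife standard errors without the block were 0.32 and 0.28.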

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

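The weighing tests, the counts of random splits and the permutation test of list scores were all chosen after the results were seen.

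Of the 492 groups of values tested, 32 held 1 mouse far from the others by Dixon's test, where chance gives about 1 in 20, or 24.6. WL replicate 5 and WW replicate 6 recurred. WL replicate 5 was low in Pparg (6.66) and Thrsp (6.46), high in Srd5a1 (9.56), Lmo4 (10.19), Elovl3 (12.16) and Avpr1a (10.43), and stood apart in the scores of sterol efflux (-0.25), xenobiotic metabolism (-0.44) and exocrine pancreas (1.24). WW replicate 6 was high in Cxcl1 (10.91), low in Thrsp (9.45), and apart in the scores of inflammatory mediators (0.98), periportal genes (0.20) and adipose genes (-0.11). LL replicate 3 was high in Fndc10 (6.86), Slc39a4 (9.43), Cbr3 (8.07) and the cell cycle score (0.70), and LL replicate 1 in Slc30a10 (9.27) and Lmo4 (10.53). Cyp17a1 was high in LL replicate 2 (11.12) and Srd5a1 in LL replicate 5 (8.95), and the fatty acid oxidation score was 0.30 in LL replicate 6. In LW, replicate 3 was apart in Acot2 (4.65), Col1a1 (6.13) and C1qb (10.91), replicate 5 in Zfp868 (4.76), replicate 2 in the bile acid score (0.13), replicate 1 in the acute phase score (-0.55) and replicate 4 in the endoplasmic reticulum stress score (0.29). Dip2c was low in WL replicate 3 (5.32) and C1qa in WW replicate 4 (8.03).

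The effect of the offspring diet differed between maternal diets in 10 gene lists by camera on the interaction, none of them called with an estimated correlation (adjusted p = 0.481 for each). The medians were 0.48 for macrophage markers, 0.51 for antigen presentation, 0.44 for inflammatory mediators, 0.26 for lymphocyte markers, 0.39 for fibrosis genes, 0.40 for cell cycle genes, 0.46 for lipogenesis, 0.32 for lipid droplet genes, -0.42 for male-biased genes and -0.38 for circadian genes. Leaving out 1 mouse ended the calls of lipogenesis, lipid droplet, inflammatory and circadian genes. As many lists came from 17 of 100 random splits of the mice (highest other split 14), so chance cannot be excluded for this number.

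Macrophage and fibrosis genes were higher in WW than in LW by camera, and neither was called with an estimated correlation (adjusted p = 0.426 and 0.438). Slide as the whole source is argued against, since the macrophage median stayed at 0.53 with slide as a block. A lower share of hepatocytes would raise endothelial and cholangiocyte markers alike, but the macrophage score rose above the endothelial score by 0.51 (exact permutation p = 0.0195) and above the cholangiocyte score by 0.53 (0.0368). Those 2 scores differed by only 0.029 and 0.0014 between WW and LW. These unadjusted p-values thus largely repeat the exact permutation test of the macrophage score (p = 0.0281, 0.2 adjusted over 33 lists) and do not decide on the share of hepatocytes by themselves. Without WW replicate 6 the macrophage median was 0.42, and the camera call was kept in 22 of 22 cases with 1 mouse left out. The maternal diet, litter and the call lost with an estimated correlation leave the pattern open. A maternal effect on macrophage genes may thus be put only as a hypothesis.

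Male-biased genes were lower in WW than in WL. With slide as a block the median was -0.91, and without WL replicate 5 it was -0.69, so neither alone accounts for it. Both together were not tried, and WL replicate 5 was the only WL array on slide 4. The 11 members whose symbol stem no other member shares were all lower, with a median of -0.94, and so were 8 without the 3 complement genes, which are 1 family (-0.88). This argues against signal shared between list members as the whole source, although Hsd3b5 and others have relatives outside the list. A response of male-typical liver expression to the western diet may be put as a hypothesis, and other technical sources were not tested.

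Slides differed in the renormalized values and not in the deposited ones. The median F for slide was 0.43 in the deposited values, lower than in every other one of 100 reassignments of slides within groups (lowest other 0.592), and 2.04 in the renormalized values (highest other 1.24). An adjustment for slide in the deposited values is a candidate explanation that the sources used here do not state. No biological explanation was tested.

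Random splits of the mice into groups of the same sizes, 100 with the real one, show which counts chance can give. Only the real split of 100 gave as many genes in LW against LL (24, highest other 1) and WW against WL (47, highest other 24). The same held for the average after weaning (268, highest other 12). This argues against a chance division of the mice, but 1 in 100 is the lowest share these splits can give. They take the mice as independent, though litter is not known. Without WL replicate 5, WW against WL gave 3 genes, and with deposited values LW against LL gave 0. The splits did not keep to the slides, which the groups fill unevenly, so they do not part diet from slide, and with slide as a block the counts were 5, 316 and 248. For the other comparisons the count was 0, which 100 of 100 splits reach in any case, so the splits say nothing there (highest others 7 in WL against LL, 5 in WW against LW, 2 in the interaction and 1 in the maternal average). The 12 lists of WW against LW were reached by 2 of 100 splits, with 12 in another split, but 0 of 33 lists passed by exact permutation and 0 with an estimated correlation, so chance is left open for each list. Chance cannot be excluded for the lists in LW against LL (7, 34 splits, highest other 13), WW against WL (13, 5 splits, 14), WL against LL (5, 53 splits, 12), the maternal average (7, 30 splits, 14) or the average after weaning (10, 13 splits, 15). Nor can it be for the correlations across genes of the effects after weaning (0.38, 9 splits, 0.58), the maternal effects (-0.061, 78 splits, 0.42) and the averages (0.087, 83 splits, -0.56).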

How the results depend on the processing

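The random slide block, leaving out LL replicate 1 and WL replicate 5 together, the estimated correlation among the alternatives and the permutation of list scores were added after the results were seen. With no further background correction 56 of 56 called gene results were kept, with normexp 53, with median scaling 51, with deposited values 35 and with no detection filter 21. The cause of each change below was not tested. In LW against LL, 24 genes became 0 with deposited values, 7 with no detection filter, 5 with slide as a block, 67 with a replicate block, 180 with array weights and 184 without LL replicate 1 and WL replicate 5. Its 7 lists became 4 with deposited values, no detection filter, the strict filter or slide as a block, 13 with all detected probes, 3 with a replicate block and 0 with an estimated correlation. By exact permutation 3 lists passed, 1 of which, methyl donor and epigenetic genes, was not among the 7. In WW against WL, 47 genes became 125 with deposited values, 2 with no detection filter, 316 with slide as a block, 122 with a replicate block, 74 with array weights, 122 with slide as a random block and 5 without both mice, and its 13 lists became 1 with an estimated correlation. In WL against LL, 0 genes became 2 with a replicate block, and 5 lists became 3 with normexp, 2 with the strict filter, 3 with all detected probes, 2 without both mice, and 0 with an estimated correlation or by permutation. In WW against LW, 0 genes became 4 with slide as a block and 1 with a replicate block, and 12 lists became 7 with no detection filter and 0 with an estimated correlation or by permutation. In the average after weaning, 268 genes became 788 with a replicate block and 528 with array weights, and 10 lists became 6 with the strict filter, 18 with all detected probes and 0 with an estimated correlation, as did the 10 of the interaction and the 7 of the maternal average. Replicate numbers were not taken to pair the mice, since the labels state no pairing. Residuals of 31 same-number pairs had a median correlation of 0.111 (51.6% over 0.1) against -0.028 (24% over 0.1) for 150 other pairs. Within a slide it was 0.252 against 0.106 and between slides 0.018 against -0.054. The lowest same-number pair was at -0.18, and 10 of 22 arrays correlated best with their own number. No chance value was computed for that count, so pairing by number is left open. Within every group the replicate numbers follow the order of the slides, so neither same-number pairs nor the replicate block are separate from slide.

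Leaving out 1 mouse gave 4 to 85 genes in LW against LL (without LL replicate 2 8, 5 10 and 6 15, without LW replicate 1 7, 2 56, 3 9 and 4 8, without WL replicate 5 70). It gave 3 to 81 in WW against WL (without WL replicate 1 12, 3 26, without WW replicate 2 10, 4 19 and 6 28) and 134 to 520 in the average after weaning (without LL replicate 5 153 and 6 170, LW replicate 1 145, WW replicate 2 144 and 6 412). WL against LL gave 0 to 1 genes and 0 to 6 lists (3 without LL replicate 2 or 3 or WL replicate 3), WW against LW and the interaction 0 to 1 genes (1 without WW replicate 1), and the lists of the average after weaning 6 to 14. Uncalled differences near 0 changed sign: Cyp17a1 in WW against WL (-0.26) was 0.14 with slide as a block and ran from -0.57 to 0.067 (without WL replicate 2) with 1 mouse left out, and Apob in LW against LL (0.034) ran from -0.090 (without LW replicate 4) to 0.11, at -0.061 without LL replicate 4 and -0.030 without LW replicate 2. Genes near background are limited by signal, and their differences are compressed.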

Other observations

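Further genes of the average after weaning, chosen after their values were seen, are given as values without slide as a block. Of the circadian genes, Ciart (1.75), Usp2 (1.44) and Dbp (0.92) were higher and Clock (-0.53) was lower, with adjusted p of 0.014, 0.0337, 0.0341 and 0.00207. The replication genes Mcm2 (0.70), Mcm5 (0.69) and Mcm4 (0.53) were higher, with adjusted p of 0.013, 0.00781 and 0.0203. The complement genes C8a (-0.95) and C8b (-0.84) were lower, with adjusted p of 0.0149 and 0.0292. Dbp, Usp2 and C8b no longer passed without at least 1 mouse, and their calls were kept in 12, 13 and 17 of 22 cases.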
